A study of Mus musculus with 6 samples.

How the data were processed

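RNA of AML-12 mouse hepatocytes was measured on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample, with 3 samples carrying a hairpin against MnSOD and 3 carrying a scrambled control hairpin. Per the labels, hairpins were delivered by retrovirus and cells were selected with puromycin, and the arrays came from different frozen batches of cells. The titles call the samples biological replicates, but the sources do not say whether each came from its own transduction, so the p-values measure the spread between these samples. The deposited values are normalized intensities on a linear scale, 1 per probe set and array. Per the submitters' processing notes the authors used RMA, whereas per the labels' design text the chips were scaled with MAS5, and the version, the background correction and the probe annotation are not given in the sources used here. All deposited intensities (100%) equalled a power of 2 of a number with 7 significant digits, within 0.02 units of the last digit, so they were antilogs of log2 values. The number of arrays limits the precision.

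The table held 35557 probe sets. An annotation table of the platform gave exactly 1 gene symbol for 21789 of them, several for 1621 and none for 12147. Symbols were updated through Entrez identifiers, which matched for 21698 probe sets in a RefSeq table of assembly GRCm38.p6 used for names only. Of the genes, 999 had more than 1 probe set, and the one with the highest mean over the 6 arrays stood for the gene. A probe set with several symbols was tested but never named. This left 21559 tested rows, of which 19938 were genes with 1 symbol, and all counts of genes refer to these. No filter on low values was used. As a guide to background, the 95th percentile of the means over all arrays of 1027 olfactory receptor genes, which hepatocytes should not express, was 4.28 on the log2 scale (19.4 intensity units). This guide was chosen after seeing the data.

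Log2 intensities were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior), group being the only term, and p-values were adjusted by Benjamini-Hochberg over all tested rows with a threshold of 0.05. Fold changes are knockdown minus control with the standard error of the fit, and other errors are SDs over 3 arrays. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether the genes of a list move one way on balance, each adjusted over 32 lists. Sod2 was left out of every list. With the preset correlation 9 lists were shifted, 6 up and 3 down, none was with an estimated correlation (lowest adjusted p 0.25, 4 lists at an unadjusted p under 0.05), and 6 were with fry. Median, mean and test did not share a sign for the NRF2, hypoxia, endoplasmic reticulum, mitochondrial unfolded protein response, endothelial, stellate cell and ribosomal protein lists, none of which was shifted. Counts adjusted over the list alone use the members of that list only. Some list members have near-identical copies in the genome, ribosomal protein genes above all, and their probe sets can take signal from these.

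The gene lists, the tests, the processing alternatives and the rule for naming genes were fixed before the data were examined. The rule named Sod2, the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap, without predicted gene models, and up to 4 members of each list by smallest p. Pdia6, Creld2, Dnajb11, Sel1l and Sparc were named after their values were seen, to complete counts of 5 or fewer, and 12 further lists were also chosen then. Samples of both groups carry replicate numbers 1 to 3. Deviations of same-numbered samples from their group means correlated at 0.30, 0.29 and 0.56 across the tested genes, all over 0.1, so the numbers were taken to pair the samples. Replicates 1 and 2 correlated more with the other's number (0.47 and 0.41), and the pairing thus rests mainly on replicate 3. The labels do not say what a number marks. A fit with the number as a block was an alternative, and its value is given where it moved a count by more than 1.5 times or changed a call.

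The scripts were tested on simulated data over 21559 rows, with the control means and the residual spread of the fit with the block. The simulated replicate effect was set and not estimated from the arrays. On the real arrays the SD of the log2 difference was 0.508 between control replicates 1 and 3, and 0.179 between 1 and 2. The rates for the fit without a block may thus be too high for these data. The fit without a block called 4% of genes changed 1.5-fold, 50% of those changed 2-fold, 94% of those changed 4-fold and 100% of those changed 8-fold, with 7 of 21319 unchanged genes. With the block it called 2%, 32%, 78% and 92%. In the same simulation camera with the preset correlation called a list of 40 genes shifted by 0.5 on the log2 scale. In a second simulation without any change it called 1 of 33 lists. Genes were simulated independently of each other, so this does not give the rate of false list calls in these data. The other alternatives were quantile normalization again, centring arrays on their medians, filters on dim probe sets, all probe sets with or without a gene, eBayes with trend and robust settings, array weights, the mean of a gene's probe sets, an offset of 16 intensity units before log2, a minimum 1.5-fold change, and each array left out in turn. The annotation's coordinates were not used, since no genome build is given for the array.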

Results

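The arrays compared AML-12 cells, a mouse hepatocyte line, carrying a retroviral hairpin against manganese superoxide dismutase (MnSOD) with AML-12 cells carrying a scrambled hairpin that targets no gene. MnSOD is the product of Sod2 and converts superoxide to hydrogen peroxide in the mitochondrial matrix. The hairpin was designed for a mild degree of silencing. Each group had 3 arrays titled as biological replicates, and each array measured the RNA of 1 sample. The median intensity over all probe sets was 27.9, 26.8 and 31 in knockdown replicates 1, 2 and 3, and 28.1, 29.3 and 33.6 in the controls. Replicates 1 and 2 resembled each other closely on the log2 scale, with a Pearson r across probe sets of 0.996 in the knockdown and 0.9973 in the controls. Replicate 3 stood apart in both groups, with r between 0.9782 and 0.9891 against its own group. Control replicates 1 and 2 were closer to knockdown replicates 1 and 2 (r 0.9833 to 0.9867) than to control replicate 3 (0.9782 and 0.9792). Knockdown replicates 1 and 2 were closer to knockdown replicate 3 (0.9891 and 0.9886) than to any control. The comparison addressed which genes differ in hepatocytes with less MnSOD.

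Sod2 itself was lower on every knockdown array than on any control array. Its only probe set read 90.7 ± 35.1 (SD, n = 3) intensity units in the knockdown and 265 ± 24.7 (SD, n = 3) in the control, so the knockdown retained 32.4% of the control level as a ratio of geometric means. The log2 fold change was −1.63 (SE 0.30), with an adjusted p of 0.037 in limma. An exact two-sided permutation test of the means gave p = 0.1, the smallest value that 3 against 3 arrays allow. The retained level was 39.8%, 47.8% and 17.8% of the same-numbered control in replicates 1, 2 and 3. The adjusted p rose to 0.069 when arrays were centred on their medians and to 0.064 when all probe sets were tested. It was 0.1 without knockdown replicate 1, 0.072 without knockdown replicate 2, 0.12 without control replicate 1 and 0.13 without control replicate 2.

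**Figure D1:**
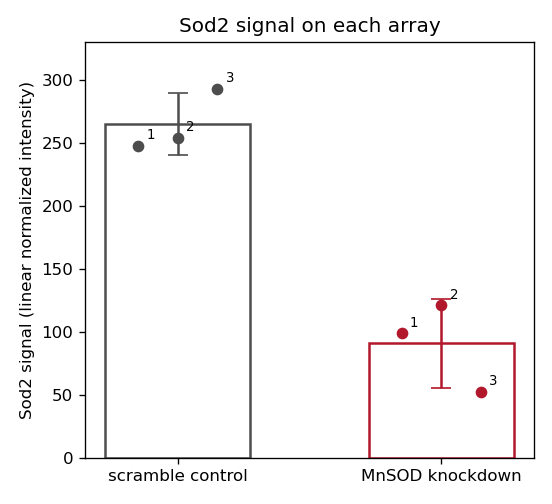
Sod2 signal in linear normalized intensity units for the scramble control and the MnSOD knockdown, with 1 point per array labelled by replicate number, bars at the group mean and error bars of 1 SD (n = 3). The knockdown arrays lay at 98.8, 121 and 52.3, all below the control arrays at 248, 254 and 293.

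The genes of largest rise acted in DNA synthesis and cell division, and several genes of largest fall in inflammation and stress responses. The 12 genes that rose most were all genes of DNA replication, nucleotide supply or cell division. They were led by Pclaf, a partner of the replication clamp, with a log2 fold change of 3.12 (SE 0.16), Uhrf1, which maintains DNA methylation at the replication fork, with 2.94 (SE 0.25), and E2f8, a cell cycle transcription factor, with 2.78 (SE 0.22). The others were Mcm5 and Mcm6 of the replicative helicase (2.76 and 2.49), the nuclease and helicase Dna2 (2.57), the primase subunit Prim1 (2.55), the DNA polymerase delta subunit Pold1 (2.54), ribonucleotide reductase subunit Rrm2 (2.66), thymidine kinase Tk1 (2.51), and the kinases Aurkb and Melk (2.71 and 2.50). The 12 genes that fell most were led by Lcn2 and Saa3, secreted products of the acute inflammatory response, with log2 fold changes of −3.46 (SE 0.40) and −3.42 (SE 0.13). They also included the glycerol channel Aqp9 (−3.17), whose knockdown mean of 4.22 lay under the background level of 4.28, and the thioredoxin-binding protein gene Txnip (−2.79). Ppp1r15a (−3.04), Ddit3 (−2.68) and Nupr1 (−2.34) are stress-response genes, Ereg (−2.56) encodes an epidermal growth factor receptor ligand, and Mmp13 (−2.46) a collagenase. Snai2 (−2.68), a repressor of epithelial genes, Blnk (−2.88), an adaptor protein gene, and Dennd4a (−2.25) completed the group. All 24 genes had adjusted p-values between 0.00082 and 0.043.

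In total, 432 genes were higher and 316 lower in the knockdown among 19938 genes with 1 symbol, at an adjusted p under 0.05 in limma. Of these, 205 rose and 123 fell at least 2-fold. With the replicate number as a block the counts were 801 higher and 623 lower, and 424 and 301 genes were called in both fits. The groups did not overlap for any of the 748 called genes, nor for 20.9% of all genes, against 10% by chance. Higher genes made up 57.8% of the calls, and 72.3% (365 against 140) after centring arrays on their medians. The higher and lower counts changed to 100 and 68 without knockdown replicate 1, 52 and 25 without knockdown replicate 2, 357 and 201 without knockdown replicate 3, 133 and 50 without control replicate 1, 118 and 33 without control replicate 2, and 1119 and 1119 without control replicate 3. Of the 24 genes, 16 passed the threshold whichever array was left out. Of the other 8, Lcn2 lost the call without knockdown replicate 2 (adjusted p = 0.065), Melk without knockdown replicate 1 or 2 (highest 0.11), Ppp1r15a and Nupr1 without knockdown replicate 1 or 2 or control replicate 2 (0.08 and 0.072), Blnk and Snai2 also without control replicate 1 (0.12 and 0.1), Aurkb without any knockdown array or control replicate 2 (0.1), and Ddit3 without any array except control replicate 3 (0.18).

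**Figure D2:**
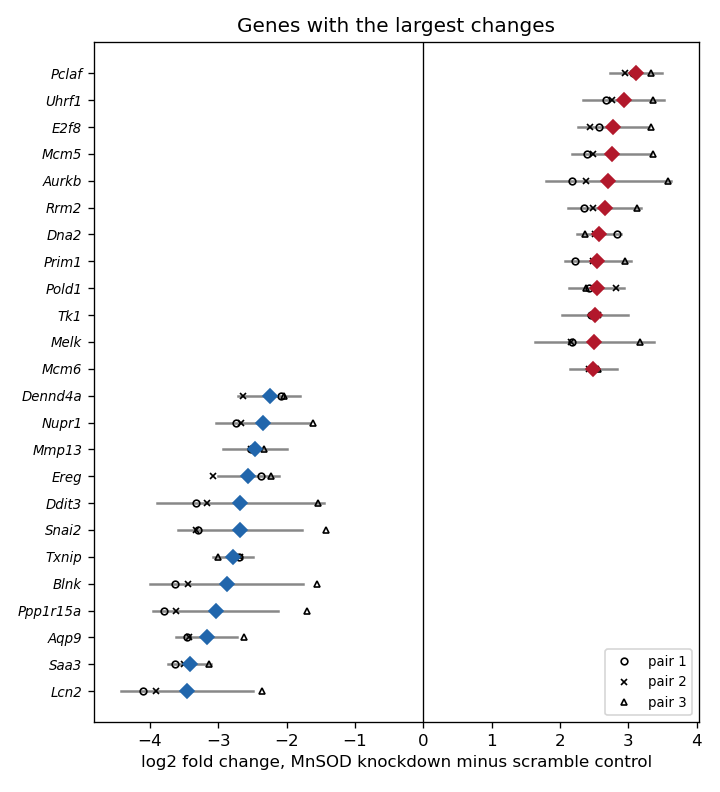
Log2 fold change of the 12 genes that rose most and the 12 that fell most, MnSOD knockdown minus scramble control, with diamonds for the difference of group means, grey lines for its 95% confidence interval and open symbols for the differences within replicate numbers 1, 2 and 3. All within-number differences lay on the same side of 0, and those of Ppp1r15a were −3.79, −3.62 and −1.7.

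Cell cycle and DNA replication genes were shifted upwards as a group. All 44 measured members had a positive log2 fold change, with a median of 1.72, and 23 passed over all genes (40 adjusted over the list alone). Besides the genes above, cyclin E gene Ccne1 rose by 2.34 (SE 0.12) and the helicase subunit Mcm2 by 1.71 (SE 0.10). The list was shifted in camera (adjusted p = 5e-37 with the preset correlation, adjusted p = 0.29 with an estimated correlation). The median difference was 1.25, 1.21 and 2.49 within replicate numbers 1, 2 and 3. Targets of p53, a transcription factor that halts the cycle after DNA damage, had a median log2 fold change of −0.49. Of 27 measured members 9 fell and 2 rose (12 and 3 adjusted over the list alone), with adjusted p = 8.8e-05 in camera and adjusted p = 0.25 with an estimated correlation. The receptor gene Eda2r fell by 1.46 (SE 0.17) and the noncoding RNA gene Pvt1 by 1.13 (SE 0.15). The 2 members that rose, Ckap2 (1.43, SE 0.12) and Gtse1 (1.57, SE 0.20), act in mitosis and the G2 phase. Eda2r lost its call without knockdown replicate 1 (adjusted p = 0.052), Pvt1 without knockdown replicate 1 or 2 or control replicate 2 (highest 0.08) and with the mean of its probe sets (−0.58, adjusted p = 0.061), and Gtse1 without knockdown replicate 2 or control replicate 1 or 2 (highest 0.07).

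Genes of cholesterol synthesis and uptake were also higher as a group. All 20 measured members had positive values, with a median of 1.63, and 7 passed over all genes, while all 20 passed adjusted over the list alone. With the replicate block 17 passed over all genes. Nsdhl rose by 1.87 (SE 0.17), the squalene synthase gene Fdft1 by 1.80 (SE 0.20), Dhcr7, which encodes an enzyme at the end of the pathway, by 1.75 (SE 0.20) and the mevalonate kinase gene Mvk by 1.24 (SE 0.11). The shift had adjusted p = 9e-20 in camera and adjusted p = 0.37 with an estimated correlation, and the medians within replicate numbers were 1.31, 1.4 and 1.83. Among 27 genes of fatty acid and triglyceride synthesis, 4 rose and none fell (9 higher and 2 lower adjusted over the list alone, 7 higher and 2 lower with the replicate block), with a median of 0.23, or 0.45 over 19 members when only the brighter probe sets were kept. They were the elongase gene Elovl6 (1.48, SE 0.13), the ATP citrate lyase gene Acly (0.83, SE 0.12), the fatty acid synthase gene Fasn (0.68, SE 0.10) and Srebf1 (0.72, SE 0.14), a transcription factor gene for this pathway. This list had adjusted p = 0.00098 in camera and adjusted p = 0.25 with an estimated correlation, and in replicates 1 and 2 alone its adjusted p was 0.059. Without knockdown replicate 1 or 2, Dhcr7 (highest adjusted p 0.056) and Fdft1 (0.065) lost their calls, as did Acly (0.11) and Fasn (0.098), which also lost them without control replicate 1 or 2. Srebf1 lost its call without any 1 array except control replicate 3 (highest 0.21).

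Genes of the integrated stress response, which ATF4 and CHOP control, were lower in the knockdown. Of 29 measured members 11 fell and none rose (20 adjusted over the list alone), with a median of −0.87. Ddit3 encodes CHOP, and Ppp1r15a encodes the phosphatase subunit that ends the translational block. The cystine transporter gene Slc7a11 fell by 1.74 (SE 0.25). The shift had adjusted p = 6.8e-15 in camera and adjusted p = 0.40 with an estimated correlation, with medians of −1.24, −1.06 and −0.41 within replicate numbers 1, 2 and 3. NF-kappaB and inflammatory genes were lower as well. Of 31 measured members 7 fell and none rose (9 adjusted over the list alone), with a median of −0.56. Besides Saa3 and Lcn2, the chemokine genes Cxcl2 (−1.87, SE 0.26) and Ccl7 (−1.04, SE 0.11) fell. The list had adjusted p = 8e-09 in camera and adjusted p = 0.37 with an estimated correlation, and its medians were −0.93, −0.72 and −0.03 within replicate numbers 1, 2 and 3. Slc7a11 and Cxcl2 lost their calls without knockdown replicate 1 or 2 or control replicate 1 or 2 (highest adjusted p 0.086 and 0.1), and Ccl7 without knockdown replicate 2 (0.056).

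Genes for mitochondrial respiration were shifted upwards by a smaller amount. Of 72 nuclear genes for oxidative phosphorylation subunits, 67 had positive values with a median of 0.32, 6 rose (9 adjusted over the list alone) and none fell. With the replicate block 17 rose. The members with the smallest p were the respiratory chain genes Ndufa3 (0.76, SE 0.12), Cox7a2 (0.72, SE 0.12), Ndufa9 (0.57, SE 0.10) and Ndufa4 (0.77, SE 0.15). The list was shifted upwards with adjusted p = 4.5e-11 in camera and adjusted p = 0.49 with an estimated correlation. The 21 measured genes of the tricarboxylic acid cycle and pyruvate oxidation had a median of 0.23, with adjusted p = 0.0033 in camera and adjusted p = 0.40 with an estimated correlation. None of them passed over all genes or adjusted over the list alone, and 2 higher and 1 lower passed with the block. Superoxide, peroxide and thioredoxin defence enzymes other than Sod2 had a median of 0.18 over 23 genes (0.28 without knockdown replicate 3, and 0.29 over 17 members when only the brighter probe sets were kept), with adjusted p = 0.0084 in camera and adjusted p = 0.29 with an estimated correlation. No member passed over all genes and 1 passed adjusted over the list alone, the one with the smallest p being the glutathione reductase gene Gsr at 0.70 (SE 0.14, adjusted p = 0.052). The 4 subunit genes lost their calls without any 1 of knockdown replicates 1 and 2 and control replicates 1 and 2, and Ndufa9 also without knockdown replicate 3 (highest adjusted p 0.14, 0.13, 0.17 and 0.2). Without control replicate 3 the tricarboxylic acid cycle list had adjusted p = 0.1 while Gsr passed (adjusted p = 0.023).

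**Figure D3:**
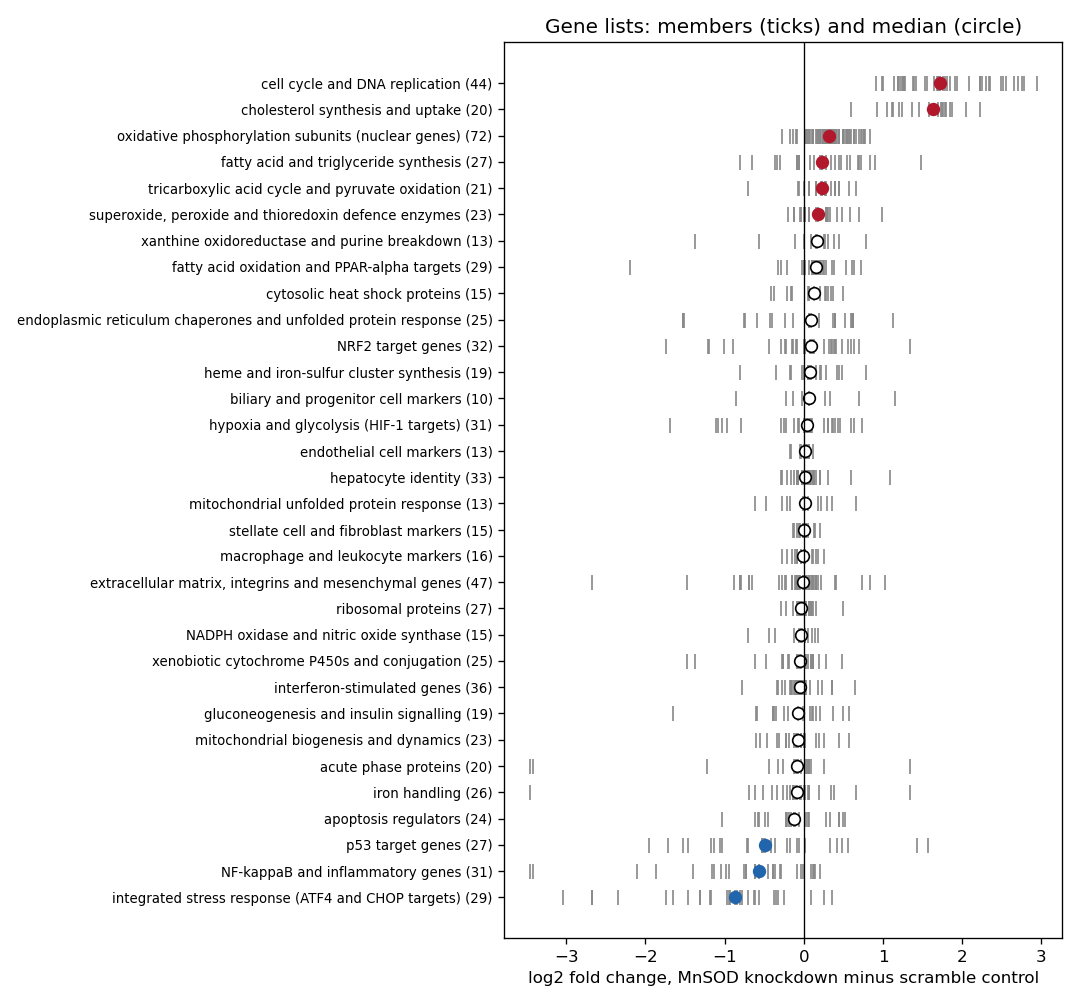
Log2 fold change, MnSOD knockdown minus scramble control, of every measured member of the 32 gene lists (ticks, number measured in brackets) and of the list median (circle), filled red or blue where camera with the preset correlation called the list shifted up or down. Cell cycle and cholesterol genes had medians of 1.72 and 1.63, and the stress response genes −0.87.

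**Figure D4:**
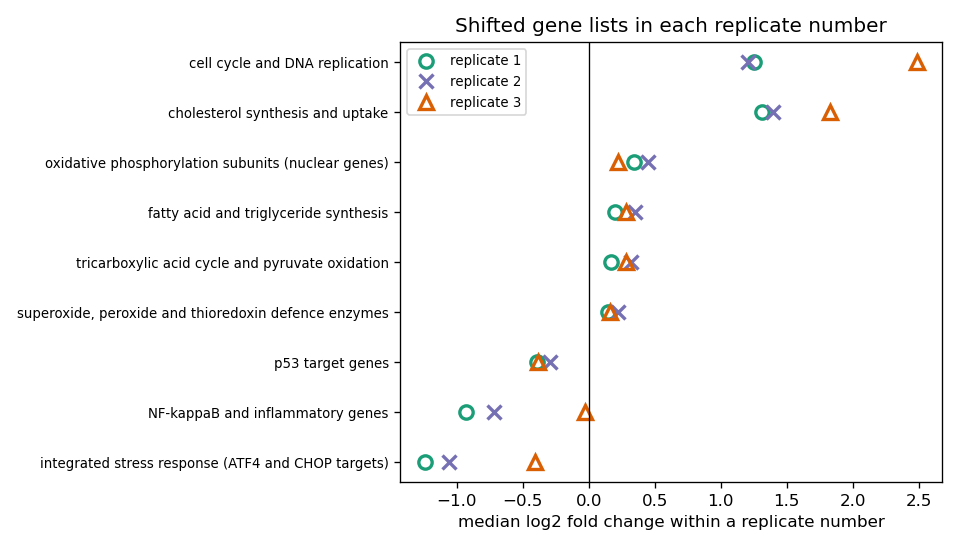
Median log2 difference of the 9 shifted gene lists within replicate numbers 1, 2 and 3, knockdown minus control. Every median lay on the same side of 0 in all replicate numbers, and that of the NF-kappaB list was −0.03 in replicate 3.

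Other stress and defence genes moved in both directions. Among 32 NRF2 target genes, the phosphogluconate dehydrogenase gene Pgd rose by 1.34 (SE 0.11), and the export pump gene Abcc4 (−1.20, SE 0.10) and Slc7a11 fell (5 higher and 3 lower adjusted over the list alone, 2 higher and 3 lower with the replicate block). The heme oxygenase gene Hmox1 had −1.21 (SE 0.25), with an adjusted p of 0.051, or 0.045 with the replicate block. The NRF2 list was not shifted (median 0.09, adjusted p = 0.53 in camera). Among 25 endoplasmic reticulum chaperone and unfolded protein response genes, 4 rose and 4 fell (10 and 5 adjusted over the list alone, 7 and 4 with the block, median 0.09, adjusted p = 0.53). The sensor genes Ern1 (−1.52, SE 0.14) and Atf6 (−1.52, SE 0.23), the chaperone gene Dnajb9 (−1.51, SE 0.16) and Sel1l (−0.59) fell, whereas Sdf2l1 (1.13, SE 0.12), Creld2 (0.62), Dnajb11 (0.62) and Pdia6 (0.61) rose. Among 31 hypoxia and glycolysis genes, Vegfa fell by 1.69 (SE 0.17) and Hif1a by 0.79 (SE 0.10), with 3 higher and 5 lower adjusted over the list alone, 2 and 2 with the block, and a list median of 0.04 (adjusted p = 0.67). Acot2, a mitochondrial thioesterase gene, fell by 2.20 (SE 0.12) and was the only called gene of 29 for fatty acid oxidation, both over all genes and adjusted over the list alone (median 0.15, adjusted p = 0.13). Leaving out knockdown replicate 2 ended the calls of Vegfa (adjusted p = 0.058), Dnajb9 (0.063) and Sdf2l1 (0.056). Leaving out any 1 of knockdown replicates 1 and 2 and control replicates 1 and 2 ended those of Hif1a (highest 0.08), Slc7a11 (0.086), Creld2 (0.13), Dnajb11 (0.14), Sel1l (0.15), Pdia6 (0.14) and Atf6 (0.11), as did knockdown replicate 3 for Pdia6 and Atf6.

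Liver-specific genes were not shifted as lists. Of 33 hepatocyte identity genes 15 lay under the background level of 4.28 in both groups, where a change could not be seen. Among all 33 genes 1 rose, over all genes and adjusted over the list alone, and none fell. It was Hnf4a, a master regulator of hepatocyte genes (1.09, SE 0.14), and the list had a median of 0.02 (adjusted p = 0.60, 2 higher with the replicate block). The cytochrome P450 gene Cyp3a13 (−1.38, SE 0.10) and Tiparp (−1.47, SE 0.22), a target of the aryl hydrocarbon receptor, fell among 25 xenobiotic genes, as they did adjusted over the list alone (median −0.05, adjusted p = 0.21). Of 47 extracellular matrix, integrin and mesenchymal genes 6 fell, with Snai2, fibronectin gene Fn1 (−1.48, SE 0.23) and Col12a1 (−0.88, SE 0.10) among them, and Sparc rose (0.84; 8 lower and 2 higher adjusted over the list alone, 7 and 2 with the block, median −0.01, adjusted p = 0.15). Of 26 iron handling genes Lcn2 and the mitochondrial iron importer gene Slc25a37 (−0.69, SE 0.12) fell and the hemopexin gene Hpx (1.34, SE 0.26) rose, with the same counts adjusted over the list alone (median −0.09, adjusted p = 0.16). Markers of macrophages and leukocytes (16 genes, median −0.01, adjusted p = 0.79), endothelial cells (13 genes, median 0.02, adjusted p = 0.96) and stellate cells and fibroblasts (15 genes, median 0.00, adjusted p = 0.97) had no called member, over all genes or adjusted over the list alone, but 11, 8 and 7 of their members lay under background in both groups. Among 10 biliary and progenitor markers Sox9 fell by 0.86 (SE 0.14) by either adjustment (median 0.07, adjusted p = 0.73). Leaving out knockdown replicate 1 or 2 or control replicate 2 ended the calls of Hnf4a, Tiparp, Fn1, Col12a1, Slc25a37, Hpx, Sox9 and Sparc (highest adjusted p 0.08, 0.093, 0.12, 0.065, 0.16, 0.18, 0.15 and 0.17), and leaving out control replicate 1 those of Tiparp, Fn1, Slc25a37, Hpx, Sox9 and Sparc.

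The remaining lists were not shifted in camera with all 6 arrays weighted alike. The 24 apoptosis regulators had a median of −0.13 (adjusted p = 0.16), and Bcl2 (−0.57, SE 0.11), which protects from cell death, and Pmaip1 (−1.03, SE 0.20), which promotes it, fell (1 higher and 3 lower adjusted over the list alone). Among 20 acute phase genes Saa3 and Lcn2 fell and Hpx rose (1 higher and 3 lower adjusted over the list alone, median −0.08, adjusted p = 0.13). Ifi27 fell by 0.78 (SE 0.10) among 36 interferon-stimulated genes by either adjustment (median −0.05, adjusted p = 0.25). Trib3 fell by 1.65 (SE 0.30, adjusted p = 0.035, or 0.056 with the replicate block) among 19 gluconeogenesis and insulin signalling genes (2 lower adjusted over the list alone or with the block, median −0.07, adjusted p = 0.24). The mitochondrial chaperone gene Hspa9 fell by 0.61 (SE 0.10) among 13 genes of the mitochondrial unfolded protein response (1 higher and 1 lower adjusted over the list alone or with the block, median 0.02, adjusted p = 0.97). The heme synthesis gene Alad rose by 0.79 (SE 0.12) among 19 heme and iron-sulfur genes (2 higher and 1 lower adjusted over the list alone, 1 and 1 with the block, median 0.08, adjusted p = 0.15). No member passed over all genes among 23 mitochondrial biogenesis genes (median −0.07, adjusted p = 0.18), 13 genes of xanthine oxidoreductase and purine breakdown (0.17, adjusted p = 0.21), 15 of NADPH oxidase and nitric oxide synthase (−0.03, adjusted p = 0.47), 15 cytosolic heat shock proteins (0.13, adjusted p = 0.53) and 27 ribosomal proteins (−0.03, adjusted p = 0.92), and adjusted over the list alone 1 purine gene was lower. With the replicate block these lists had 2 lower biogenesis genes, 1 lower purine gene and 1 higher ribosomal protein gene. Leaving out knockdown replicate 1 or 2 or control replicate 1 or 2 ended the calls of Bcl2 (highest adjusted p 0.18), Pmaip1 (0.21), Ifi27 (0.092), Trib3 (0.17), Hspa9 (0.13) and Alad (0.11), and leaving out knockdown replicate 3 those of Bcl2 and Alad. Centring arrays on their medians raised the median log2 fold change over all tested genes from 0.007 to 0.091. Of the 23 lists not shifted, the medians of 11 reached or crossed 0 under at least 1 scaling, so their sign depends on the scaling.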

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

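Probe sets for which no gene was given here also carried differences. When all probe sets of the arrays were tested together, 85 of the 12147 without a gene differed between knockdown and control, 31 of them higher and 54 lower, with log2 fold changes from −2.25 to 2.54. This was a smaller share than among the 19938 genes with 1 symbol, of which 272 were higher and 149 lower in the same test. They were singled out because they lie outside the named genes on which the comparisons rest, and no explanation for them was tested.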

How the results depend on the processing

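No gene named in the text and none of the 9 shifted lists changed direction under any alternative. Calls were less stable. Centring arrays on their medians left 140 lower genes and Sod2 at −1.54 (adjusted p = 0.069), and testing all probe sets left 272 higher and 149 lower genes with Sod2 at −1.63 (adjusted p = 0.064), where more probe sets enter the adjustment. The replicate block gave 801 higher and 623 lower genes, and besides Hmox1 and Trib3 it changed no call of a named gene, nor of a shifted list in camera with the preset correlation. Of the 93 named genes other than Sod2, 18 lost their calls with centring (Ddit3, Atf6, Bcl2, Cox7a2, Creld2, Dnajb11, Hpx, Hspa9, Ndufa4, Pdia6, Sel1l, Tiparp, Trib3, Mrpl18, Psmc3, Wars, Sars and Atp6v1h). With all probe sets 21 did (Ddit3, Bcl2, Dnajb11, Hpx, Ndufa4, Ndufa9, Pdia6, Pmaip1, Sel1l, Slc25a37, Sox9, Sparc, Srebf1, Trib3, Mrpl18, Mrpl45, Psmd13, Psmc3, Wars, Sars and Atp6v1h), and with trend and robust settings 6 did (Bcl2, Pmaip1, Srebf1, Mrpl45, Psmc3 and Atp6v1h). Quantile normalization ended the calls of Sparc, Srebf1 and Mrpl45, the offset those of Ddit3, Hpx and Pmaip1, and the looser filter on dim probe sets those of Sars and Atp6v1h. Conversely, Hmox1 and Gsr, not called in the main fit, gained a call in 8 and 6 of 18 settings, left-out arrays included. Array weights gave 2486 and 2188. Leaving out 1 array gave 52 to 1119 higher genes, 25 to 1119 lower genes, 9 to 12 lists and a Sod2 log2 fold change of −1.88 to −1.27 (adjusted p up to 0.13). The arrays of replicates 1 and 2 alone (2343 and 1932 genes) and a block of replicate 3 against the others (1496 and 1222) were chosen after seeing the data and gave more calls. No list was shifted with an estimated correlation, without or with the replicate block (0 and 0 lists in camera, 4 and 0 at an unadjusted p under 0.05), and fry gave 6 lists without and 5 with the block. Without the block fry did not call the integrated stress response (adjusted p = 0.078), oxidative phosphorylation (0.2) and tricarboxylic acid cycle (0.11) lists. In fry the block ended the calls of the cell cycle (adjusted p = 0.056), NF-kappaB (0.16) and fatty acid synthesis (0.079) lists and added those of the tricarboxylic acid cycle and iron handling lists (0.048 each). In camera with the preset correlation the 9 called lists kept their calls, except tricarboxylic acid cycle genes without control replicate 3 (adjusted p = 0.1) and fatty acid synthesis genes in replicates 1 and 2 alone (adjusted p = 0.059). Calls were gained by fatty acid oxidation (adjusted p = 0.028, 0.0072 and 0.008) and acute phase genes (0.045, 0.028 and 0.041) with array weights, without knockdown replicate 3 and in replicates 1 and 2 alone, by heme and iron-sulfur genes without knockdown replicate 3 (0.0091), and by mitochondrial biogenesis (0.038) and hypoxia genes (0.013) without control replicate 3. The remaining counts of genes stayed within 1.5 times of those reported. For the moves under centring, array weights, blocks and left-out arrays the cause was not tested. Lost calls were most frequent where an array of replicates 1 or 2 was left out. Of the 93 named genes, 51, 57, 40 and 48 lost their calls without knockdown replicates 1 and 2 and control replicates 1 and 2. Without knockdown replicate 3 it was 12, and without control replicate 3 it was 0. It was also 0 in replicates 1 and 2 alone and with replicate 3 against the others as a block. Genes changed less than 2-fold were mostly missed in simulated data, and 14 called genes had a group mean near background, where fold changes are understated.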

Other observations

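The 12 lists in this part and the tests of replicate 3 and of transcript length were chosen only after results had been seen, so the lists that hold leading genes are not independent evidence of direction. Of 38 genes for replication licensing and DNA synthesis, 31 rose (37 adjusted over the list alone; median 1.59, adjusted p = 3.5e-50 in camera, adjusted p = 0.068 with an estimated correlation), among them the ligase gene Lig1 (2.28, SE 0.14) and the polymerase alpha gene Pola2 (1.82, SE 0.11). Their median was 1.39, 1.49 and 1.73 within replicate numbers 1, 2 and 3. Of 38 genes for mitosis and chromosome segregation, 7 rose (28 adjusted over the list alone and 11 over all genes with the replicate block; median 1.66, adjusted p = 3e-20, adjusted p = 0.23 with an estimated correlation), for example Kif20a (2.35, SE 0.26), and the medians were 1.11, 1.04 and 2.79. Of the 39 genes first put on each of these lists, 17 and 21 are also on the cell cycle list. Of 21 genes of homologous recombination and Fanconi repair 7 rose (17 adjusted over the list alone and 11 with the block; median 1.12, adjusted p = 1.7e-15, adjusted p = 0.11 with an estimated correlation), led by Rad54l (2.35, SE 0.11) and Fanci (2.10, SE 0.20). Of 27 immediate early genes 8 fell (15 adjusted over the list alone; median −0.67, adjusted p = 2.6e-14, adjusted p = 0.068 with an estimated correlation), such as Egr1 (−1.49, SE 0.16) and Dusp4 (−0.94, SE 0.10). Of 8 ligands of the epidermal growth factor family all were negative and Ereg fell (2 adjusted over the list alone; median −0.50, adjusted p = 0.00022, adjusted p = 0.068 with an estimated correlation). Kif20a lost its call without knockdown replicate 2 (adjusted p = 0.065) and Dusp4 without knockdown replicate 1 or 2 or control replicate 2 (highest 0.056).

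Of 30 lysosome and autophagy genes Sqstm1 (−1.09, SE 0.13), Npc1 (−1.03, SE 0.17) and Atp6v1h (−0.49, SE 0.10) fell (6 adjusted over the list alone and 5 with the block; median −0.17, or −0.1, 0.01 and −0.53 within replicate numbers 1, 2 and 3, adjusted p = 3.6e-05, adjusted p = 0.34 with an estimated correlation). Of 18 cytosolic aminoacyl-tRNA synthetase genes Wars (−0.78, SE 0.14) and Sars (−0.59, SE 0.12) fell (9 lower and 2 higher adjusted over the list alone; median −0.39, or −0.54, −0.49 and 0.05 within replicate numbers, adjusted p = 0.0014, adjusted p = 0.34 with an estimated correlation). Of 34 proteasome genes Psmd13 (0.74, SE 0.14) and Psmc3 (0.58, SE 0.11) rose, as they did adjusted over the list alone (median 0.27, adjusted p = 0.00013, adjusted p = 0.34 with an estimated correlation). Among 19 FoxO and quiescence genes Klf9 fell by 1.22 (SE 0.14) and Rbl1 rose by 1.55 (SE 0.15), with 5 lower and 1 higher adjusted over the list alone and 3 lower and 1 higher with the block (median −0.22, adjusted p = 0.017, adjusted p = 0.14 with an estimated correlation). Of 16 matrix metalloproteinase genes Mmp13 fell, by either adjustment, and the list was not shifted (median −0.02, adjusted p = 0.28). Sod2 is a known NF-kappaB target, and 4 of the 31 other members of that list had a lower log2 fold change, not all of them called. Sod2 retained 39.8%, 47.8% and 17.8% of the same-numbered control in replicates 1, 2 and 3. The list medians were −0.93, −0.72 and −0.03, so Sod2 was lowest where the list hardly moved. Klf9 lost its call without knockdown replicate 1 or 2 or control replicate 2 (highest adjusted p 0.065), and Sqstm1 (0.063), Npc1 (0.14), Atp6v1h (0.19), Wars (0.17), Sars (0.2), Psmd13 (0.18) and Psmc3 (0.19) without any 1 of knockdown replicates 1 and 2 and control replicates 1 and 2, with Atp6v1h, Wars and Sars also losing it without knockdown replicate 3.

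Other groupings of the arrays were compared. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 432 higher and 316 lower genes and every other split 0 in either direction in limma (39 to 2553 genes at an unadjusted p under 0.05, against 3324), so 1 split gave as many in each case. Every other split mixes knockdown and control arrays on both sides. A real group difference would widen the spread in such a split and hold its gene calls down. For gene lists 4 splits shifted as many as the real one, which shifted 9, and the highest other shifted 11. These 3 others put knockdown replicates 1 and 2 together with 1 control array (10, 11 and 10 lists), so camera with the preset correlation also called lists in splits that mix knockdown and control arrays. Cell cycle genes had the smallest adjusted p in the real split (5e-37), and the smallest of any list in any other split was 4.8e-20, for cell cycle genes too. Other lists had smaller adjusted p-values in camera in mixed splits than in the real one. With knockdown replicates 1 and 2 joined by control replicate 1 or 2, oxidative phosphorylation genes had 3.7e-18 and 8e-19, against 4.5e-11. With control replicate 3 joined instead, integrated stress response genes had 1.7e-18, against 6.8e-15. With the replicate block 9 lists were shifted. Of the 4 splits that part all pairs, the 3 others gave 0 genes and 10, 2 and 4 lists.

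In camera with the preset correlation, though not with an estimated one (adjusted p = 0.29, 0.40 and 0.37), cell cycle genes were shifted up and stress-response and inflammatory genes down. The 3 lists kept at least 0.86 of their median shift under either scaling. Centring moves all fold changes alike, and it took the median over all tested genes only from 0.007 to 0.091. List shifts of this size could therefore hardly shrink, so the test cannot decide whether scaling between arrays plays a part. Replicate 3 alone does not account for the lower stress and inflammatory genes, which kept at least 1.38 of their shift in replicates 1 and 2, but for the cell cycle list the share was 0.72, which leaves a part of the rise resting on replicate 3. A candidate explanation is that the control cultures were denser or more depleted of nutrients, and 2 of 3 lists moved as that predicts (lysosome and FoxO genes lower, though with adjusted p = 0.34 and 0.14 with an estimated correlation, and 0.10 and 0.13 in replicates 1 and 2 alone), while 23 YAP target genes went the opposite way (median −0.15, adjusted p = 0.017, adjusted p = 0.23 with an estimated correlation and 4.5e-05 in replicates 1 and 2 alone; 0 called over all genes, 1 lower with the block and 2 lower adjusted over the list alone). Culture state and an effect of MnSOD loss itself therefore cannot be told apart here, as the labels give no density at harvest. Any other difference between the cells carrying each hairpin would also be shared by a whole group. Such differences were not tested and cannot be told apart from MnSOD loss either.

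The small rise of oxidative phosphorylation genes was set against transcript length. A labelling bias towards short transcripts would also lift the cytosolic ribosomal protein genes, and their median lay lower by 0.35 (bootstrap SE 0.04). But they were also brighter (median level 12.16 against 9.21 on the log2 scale) and transcript lengths were not used, so this bias stays open. Mitochondrial ribosomal protein genes had a median of 0.28 over 70 genes (adjusted p = 2.7e-08, adjusted p = 0.30 with an estimated correlation), with 2 higher, Mrpl18 (1.24, SE 0.22) and Mrpl45 (0.70, SE 0.14), 0 adjusted over the list alone and 9 with the replicate block, so a rise shared by some genes for mitochondrial proteins may be involved. Genes of the mitochondrial unfolded protein response (median 0.02, adjusted p = 0.97) and of mitochondrial biogenesis (−0.07, adjusted p = 0.18) were not shifted, and proteasome genes, which are not mitochondrial, had a median of 0.27 (adjusted p = 0.00013, adjusted p = 0.34 with an estimated correlation). Mrpl18 and Mrpl45 lost their calls without any 1 of knockdown replicates 1 and 2 and control replicates 1 and 2, and Mrpl45 also without knockdown replicate 3 (highest adjusted p 0.17 and 0.2).

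Replicate 3 stood apart in both groups, with 4164 genes higher and 1974 lower than in replicates 1 and 2. Signal compression alone would shift genes by brightness only. Oxidative phosphorylation genes were lower in replicate 3 by a median of −0.32, at percentile 0.03 of 10000 random lists matched on brightness. Random lists lack the correlation between members of such a list, so this percentile may be too extreme. Ribosomal protein genes were at −0.15, at percentile 25.7, no further than other bright genes. Only a low percentile of both lists was to count against compression alone, so the test does not decide. Median shifts in replicate 3 were 0.09 for the dimmest genes and −0.13 for the brightest. That is the direction that compression would give, so compression may be part of the difference. Identical values made up 0.31% to 0.38% of the tested rows between any arrays of replicates 1 and 2, within or across groups. They made up 0% between those arrays and replicate 3, and 0.032% between the replicate 3 arrays. Such a pattern goes with replicate 3 having been processed apart from the others. Whether its cells also came from another batch cannot be told with 1 array per group.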
